A study of Homo sapiens with 9 samples.

How the data were processed

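Gene expression was measured with 1-colour Affymetrix PrimeView Human arrays in 9 samples. According to the labels, 3 samples were the undifferentiated human embryonic stem cell line H9 (hESC) at passage 38, 3 were neural stem cells derived from it (NSC) at passage 2, and 3 were cardiomyocytes derived from it (CM) on day 25 of differentiation. The labels number the replicates from 1 to 3 in each group and do not say whether these were separate cultures, separate differentiations or repeated arrays.

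The deposited values were probe set summaries in units of intensity on a linear scale, which the authors made with RMA, the only tool the labels name and with no version given. The scale was read from the values: the median per array lay between 104 and 105 and the upper quartiles reached 449, so log2 was taken before any test. The written design had assumed log2 values and provided for this step. Values were used as deposited, with no further scaling. The table held 49395 probe sets, of which 102 were control probe sets and were left out of the gene tests. Of the others, 44988 named 1 gene, 1832 named several genes and 2473 named no gene in the array annotation. Only those with 1 gene were used, and a gene was represented by its probe set with the highest mean over all 9 arrays. This gave 18132 genes, of which 11734 had more than 1 probe set. No filter on low values was applied.

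A linear model with a mean per group was fitted to all 9 arrays at once with limma 3.58.1 in R 4.3.3, followed by its moderated test and Benjamini-Hochberg adjustment over all genes within each of the 3 comparisons. A gene was called with an adjusted p under 0.05 and an absolute log2 difference of at least 1. A gene was group-specific when it was called in the same direction against both other groups. The overlap of the changes in NSC and CM was set against that of independent lists, and their covariance, since they share the hESC arrays, against 100 simulations of unchanged groups.

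The tests, the thresholds, 29 gene lists with 572 members (533 measured) and the rule for naming genes were fixed before the data were examined. The rule took the 6 largest rises and 6 largest falls per comparison among called genes whose arrays did not overlap, up to 4 called members per list, 9 measured marker genes in every comparison, 5 genes per group among the group-specific ones, and exceptions within a list. A gene named outside this rule is said to have been chosen after its values were seen. Lists were tested with limma's camera at a preset correlation between genes of 0.01, then with an estimated correlation, and with fry as an alternative. Adjustment was over the 29 lists within a comparison, and a list was called with an adjusted p under 0.05. Calls adjusted over the list alone gave the same counts as calls over all genes in all 29 lists and 3 comparisons.

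Arrays have no read depth, so the number of arrays limits the precision, and the median standard error of a log2 difference was 0.0708. A floor for weak signals was chosen after the data were seen: per array, the 95th percentile of 20 control probe sets without a target, at log2 4.61 to 4.97. Where all arrays of the dimmer group lay at or below it, the fold is given as a lower bound against the floor. Control values of single measures were compared with exact two-sided permutation tests, whose smallest possible p is 0.1 with 3 arrays against 3. The pipeline was tested on simulated data built with the same group sizes. It called 46% to 54% of genes with a true log2 difference of 1, 100% of those at 1.5 and 2, and 0 unchanged genes.

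Alternatives fixed beforehand were a replicate block, 3 scalings, a filter on low values, 3 choices of probe set, a trended robust prior, array weights, fits of 2 groups, 2 other thresholds, other set tests, and leaving out each array. Scaling to the poly-A spikes, the beta-actin 3' minus 5' difference as a covariate, and leaving out NSC replicate 3 with CM replicate 3 were added after the data were seen. The poly-A spike scaling moves all genes of an array by the same amount, so a list keeps its place among the other genes. Its camera adjusted p can still change greatly, for pluripotency in NSC versus hESC from 1.52e-13 to 1.16e-50. A list call gained under this scaling is therefore no added support. The way in which a list was judged to change direction between settings was revised once after its first output was seen, and follows the direction of the set test, except that a called list whose median changed sign also counts.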

Results

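Messenger RNA levels were measured on gene expression arrays in H9, an established human embryonic stem cell line (hESC), and in 2 populations differentiated from it, neural stem cells (NSC) and cardiomyocytes (CM). Each group had 3 arrays. The hESC were collected at passage 38, the NSC at passage 2 and the CM on day 25 of differentiation. The series set out to compare the gene expression profiles of these 3 populations. The median signal per array was 104 to 105 intensity units, and 18132 genes were compared. Levels are given as log2 signal, mean ± SD of 3 arrays, and differences as log2 differences with the standard error (SE) of the fit. The p-values measure only the spread between these arrays, which may be technical.

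Arrays of the same group were nearly alike and the groups stood far apart. Across genes, which are not independent replicates, Pearson's r was 0.998 to 0.999 within hESC, 0.998 within NSC and 0.997 to 0.998 within CM. Between groups it was 0.921 to 0.922 for hESC and NSC, 0.880 to 0.883 for NSC and CM, and 0.869 to 0.871 for hESC and CM. The first principal component held 63.0% of the variance and the second 35.2%.

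**Figure D1:**
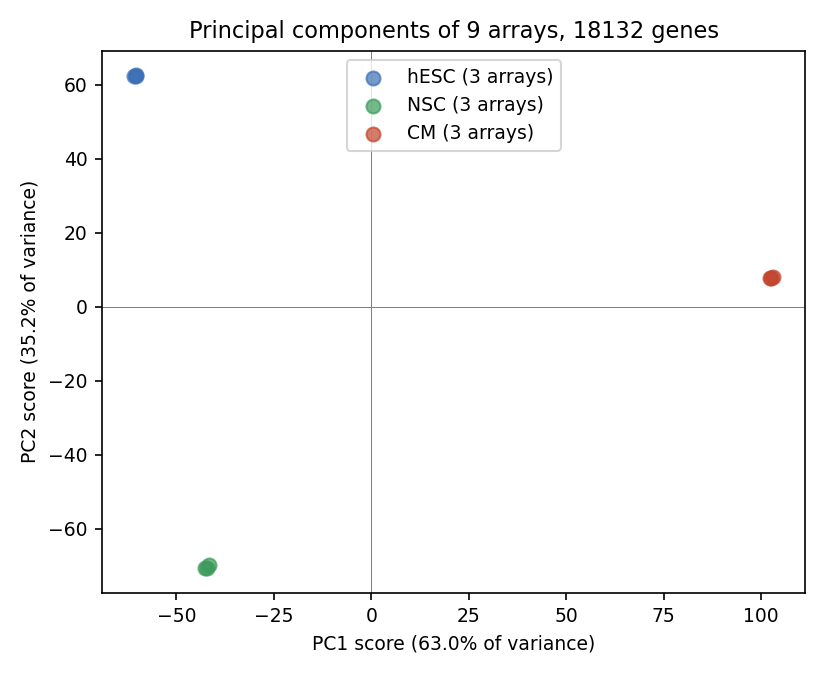
Scores of the 9 arrays on the first 2 principal components of 18132 genes, each point an array coloured by group. The 3 arrays of each group fall close together, and PC1 and PC2 hold 63.0% and 35.2% of the variance.

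Some of the control probe sets differed between the groups. The poly-A spikes, bacterial transcripts meant to be added to the RNA before labelling, had a mean level of 8.01 ± 0.26 in hESC, 7.73 ± 0.10 in NSC and 7.34 ± 0.09 in CM. The difference between CM and hESC was -0.67, with an exact permutation p of 0.1, the smallest possible with n = 3 per group. The hybridization controls, added after labelling, had 12.32 ± 0.07, 12.33 ± 0.03 and 12.28 ± 0.05. The 3' minus 5' difference of beta-actin, which grows as RNA is degraded or copied incompletely, was 1.39 ± 0.04 in hESC, 1.48 ± 0.14 in NSC and 2.02 ± 0.30 in CM, with 2.36 on CM replicate 3. That of GAPDH was 0.68 ± 0.003 in hESC, 0.82 ± 0.16 in NSC and 1.00 ± 0.05 in CM. On NSC replicate 3 it was 1.01. Its exact permutation p against hESC was 0.1 for NSC and for CM. If the arrays were scaled to the poly-A spikes instead, a setting added after the data were seen, the median of all genes shifted by 0.28 for NSC versus hESC, 0.67 for CM versus hESC and 0.39 for CM versus NSC. The differences in the text are relative to the scale as deposited, which gave the arrays like medians.

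**Figure D2:**
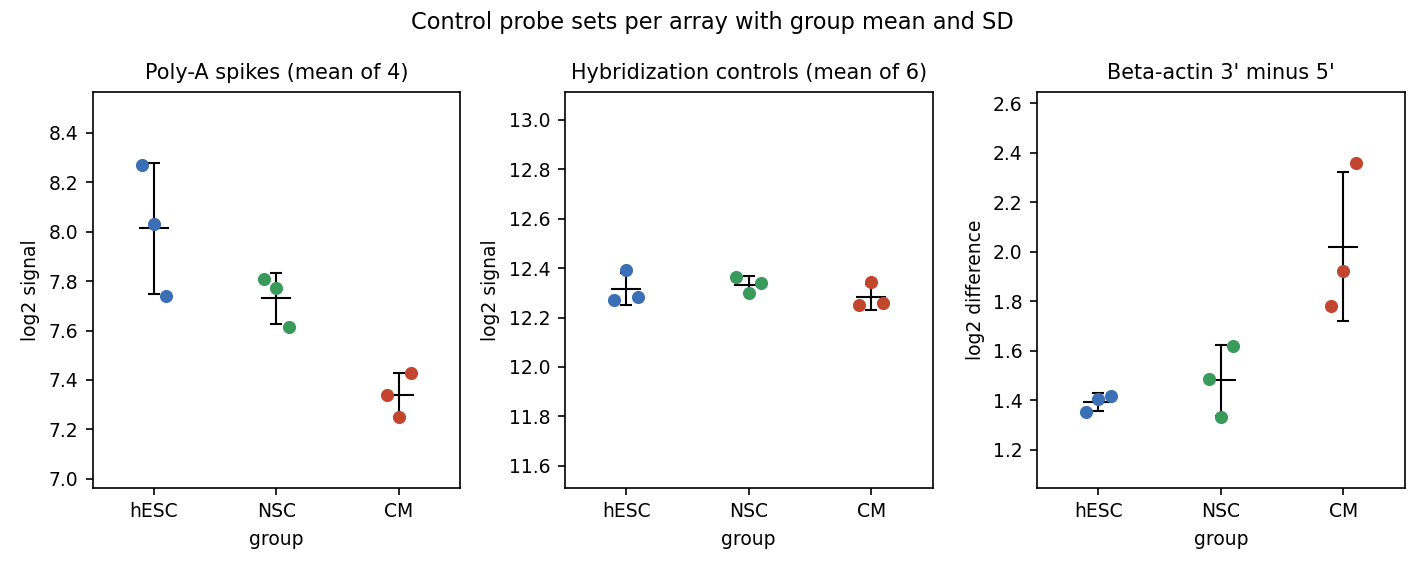
Log2 signal of the poly-A spikes (mean of 4 probe sets) and hybridization controls (mean of 6), and the log2 3' minus 5' difference of beta-actin, per array (points) with group mean and SD (bars). The poly-A spikes have a mean of 8.01 in hESC and 7.34 in CM, the hybridization controls 12.32 and 12.28, and the beta-actin difference 1.39 and 2.02.

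The comparison of NSC with hESC asks how the neural population differed from the cells it came from. In NSC, genes of neural progenitors and neurons were higher, and genes of pluripotency and of epithelial cell contacts were lower. Among the largest rises was that of COL3A1, a chain of fibrillar collagen, from 3.88 ± 0.25 in hESC to 12.81 ± 0.04 in NSC, at least 259-fold. RFX4, a transcription factor of the developing brain, rose at least 112-fold. Among the largest falls was that of L1TD1, an RNA-binding protein of pluripotent cells, from 12.91 ± 0.03 to 4.57 ± 0.21, at least 255-fold.

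Of 18132 genes, 1446 were called higher in NSC and 1451 lower. With the poly-A spike scaling these counts were 2134 and 1044. Other large rises were those of HOXB2, a positional regulator of the hindbrain, at least 65.7-fold, IL13RA2, a receptor chain for interleukin 13, at least 64.5-fold, PRDM8, a transcriptional regulator of neural development, at least 40.1-fold, and MEIS2, a cofactor of HOX proteins, 148-fold. Other large falls were those of the cell adhesion gene CDH1, at least 175-fold, POU5F1, a core regulator of pluripotency, 260-fold, its pseudogene copy POU5F1P3, at least 184-fold, APELA, a peptide hormone of pluripotent cells, at least 104-fold, and ESRP1, a splicing regulator of epithelial cells, at least 71.7-fold. POU5F1 and POU5F1P3 were each read by a probe set that can hybridize to several transcripts, so their signals may not be separate.

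Of 26 measured pluripotency genes, 22 fell, 0 rose and 4 were not called, with a median log2 difference of -2.86 (-2.80 with weak values set to the floor, the signal of control probe sets without a target). The list was called lower by camera, adjusted p = 1.52e-13, and 0.00346 with an estimated correlation. NANOG fell from 10.90 ± 0.06 to 4.02 ± 0.02, which is at the floor, at least 63.5-fold (adjusted p = 2.94e-12). LIN28A, an RNA-binding protein that blocks let-7, fell 3.41-fold and stayed at 12.07 ± 0.09. Of 20 genes of epithelial junctions and keratins, 17 fell and 3 were not called, with a median of -2.81. That list's camera adjusted p was 1.03e-11, and 0.00346 with an estimated correlation. EPCAM, a surface adhesion protein, fell 58.7-fold and KRT19, a keratin, 52-fold.

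Of 26 genes of neural stem and progenitor cells, 14 rose, POU3F1 fell and 11 were not called. Their median was 1.52 (1.39 with weak values set to the floor), with a camera adjusted p of 1.25e-06, and 0.0108 with an estimated correlation. PAX6, a regulator of neural progenitors, rose from 5.88 ± 0.11 to 12.04 ± 0.11 (log2 difference 6.16, SE 0.08, adjusted p = 1.50e-11). POU3F2, a neural transcription factor, rose at least 83.6-fold, and HES5, a Notch target that keeps progenitors undifferentiated, 96.1-fold. NES, an intermediate filament of neural progenitors, rose 4.58-fold. SOX2, shared by pluripotent and neural progenitor cells, was at 12.91 ± 0.02 in NSC and differed from hESC by -0.08 (SE 0.07, adjusted p = 0.333). Of 27 neuronal genes, 22 rose and 5 were not called, with a median of 2.99 (2.76 with weak values set to the floor). Their camera adjusted p was 2.13e-12, and 0.018 with an estimated correlation. Among them, DCX, a microtubule protein of young neurons, rose 38.9-fold, MAP2, a microtubule protein of dendrites, 36.2-fold, and ELAVL4, a neuronal RNA-binding protein, at least 46.7-fold.

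Of 22 genes of midbrain, hindbrain and spinal cord patterning, 5 rose and 17 were not called, among the 5 HOXB2, HOXB3 (at least 27.9-fold), HOXA2 and GBX2 (6.51-fold). Of 16 forebrain genes, SP8 rose 3.94-fold, 4 fell and 11 were not called. The 4 were OTX2 (67.7-fold lower), FEZF1, HESX1 and SIX3. Neither list was called by camera, with adjusted p of 0.0743 and 0.608. The first was called higher with a filter on low values (median 4.17 over the members left, adjusted p = 0.0108). That filter drops members weak in all groups and keeps those high in any group, so this call is no added support. Under the poly-A spike scaling the first list was called higher (adjusted p = 2.63e-06) and the forebrain list lower (adjusted p = 0.00257). The median of the forebrain list turned from -0.05 to 0.23. That scaling shifts all genes of an array alike, so these calls add no support either.

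Of 16 genes of the Notch pathway, which controls when progenitors differentiate, 7 rose and 9 were not called (camera adjusted p = 0.00558, adjusted p = 0.313 with an estimated correlation). They included the ligand DLL1, 18.8-fold higher. Of 17 fibroblast and stroma genes, 8 rose, with a median of 0.80 (0.46 at the floor), among them COL3A1 and the matrix proteoglycans LUM (at least 19.6-fold) and DCN (at least 12.3-fold), and THY1, a surface protein also found on hESC, fell 18.7-fold (camera adjusted p = 0.0114, adjusted p = 0.0937 with an estimated correlation). Of 18 glycolysis genes, 6 fell and 12 were not called, with LDHA, which makes lactate, 3.93-fold lower (camera adjusted p = 0.000245, adjusted p = 0.0937 with an estimated correlation). Of 27 cardiac sarcomere genes, 8 fell, among them TNNI3, ACTC1 and TPM1, and MYOM2 rose. That list had a median of -0.06, which became 0.22 under the poly-A spike scaling while its test stayed lower (camera adjusted p = 0.0388, adjusted p = 0.119 with an estimated correlation). Of 32 cell cycle genes, MKI67 and RRM2 rose, BUB1 and CCNE1 fell and 28 were not called (camera adjusted p = 0.995). MKI67, a protein of dividing cells, was at 9.55 ± 0.04 in hESC and 10.68 ± 0.02 in NSC.

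The other 18 lists were not called in this comparison, with camera adjusted p between 0.061 for neural crest and 0.995 for primitive streak and mesoderm, but neural crest was called higher with the replicate block (0.0353), the mean of probe sets (0.00783), the poly-A spike scaling (0.00853) and without hESC replicate 3 (0.0422), and endothelium lower with the filter on low values (0.0365). With an estimated correlation the camera adjusted p of neural crest was 0.397. The calls under the poly-A spike scaling and the filter add no support, for the reasons given for the patterning lists. The rise of MKI67 and RRM2 was not called with the mean of all probe sets of a gene, at 0.82 and 0.67. RRM2 was at 0.25 without _x_at probe sets, a kind that can hybridize to several transcripts.

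The comparison of CM with hESC asks how the cardiac population differed from the cells it came from. All 27 measured genes of the cardiac sarcomere, the contractile unit, rose, with a median log2 difference of 6.93 (6.78 with weak values set to the floor). Pluripotency genes and genes of dividing cells fell. Among the largest rises was that of PLN, a regulator of the cardiac calcium pump, from 3.96 ± 0.05 in hESC to 14.27 ± 0.02 in CM, at least 708-fold. Among the largest falls was that of LIN28A, from 13.84 ± 0.02 to 5.04 ± 0.31, 444-fold.

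Of 18132 genes, 2087 were called higher in CM and 2378 lower. With the poly-A spike scaling these counts were 4639 and 1091, so that the share of called genes that were higher was 81.0% in place of 46.7%. Cyclic loess gave 2373 and 2013, a share of 54.1%. In CM, the poly-A spikes were lower and the beta-actin 3' minus 5' difference was larger than in hESC, by 0.63. Other large rises were those of COL3A1, at least 542-fold, SMPX, a small protein of striated muscle, at least 429-fold, ANKRD1, a muscle stress protein of the sarcomere, at least 321-fold, MYOZ2, a protein of the sarcomere's Z disc, at least 302-fold, and MYL2, a myosin light chain of ventricular muscle, 707-fold. Other large falls were those of the transcription factors ZIC2 (at least 362-fold), OTX2 (at least 165-fold), ZIC5 (at least 185-fold) and SOX2 (239-fold), and of POU5F1P3, whose mean in CM lay below the floor.

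The sarcomere list's camera adjusted p was 1.59e-15, and 0.00155 with an estimated correlation. MYH6, the atrial myosin heavy chain, rose from 5.45 ± 0.11 to 14.65 ± 0.01 (log2 difference 9.20, SE 0.09, adjusted p = 1.08e-12), and MYH7, the ventricular one, from 4.79 ± 0.09 to 13.40 ± 0.08. The MYH6 probe set can hybridize to several transcripts, and the sequences of these myosins are alike. Of 19 cardiac transcription factors, 15 rose and 4 were not called, namely TBX20, TBX3, IRX4 and HEY2, with a median of 3.89 (3.38 with weak values set to the floor) and a camera adjusted p of 1.77e-07 (0.00673 with an estimated correlation). NKX2-5, an early regulator of heart formation, rose 38.5-fold, GATA6 at least 104-fold, and MYOCD, a coactivator in muscle, at least 69-fold. Of 23 genes of calcium handling and ion channels, 17 rose, GJA1 fell and 5 were not called (median 2.35, 2.18 at the floor, camera adjusted p = 3.24e-07, and 0.00748 with an estimated correlation). SLC8A1, the sodium-calcium exchanger, rose 107-fold and CASQ2, a calcium store protein, at least 95.4-fold.

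Most markers of both heart chambers rose. Several of them also belong to the sarcomere, transcription factor or ion channel lists, so the chamber lists are not separate evidence. Of 9 atrial markers, 7 rose and 2 were not called (median 3.30, camera adjusted p = 6.81e-05, and 0.03 with an estimated correlation), among them MYL7 at 15.04 ± 0.03 and the hormone NPPA, 222-fold higher. Of 9 ventricular markers, 6 rose, GJA1 fell and 2 were not called, the transcription factors IRX4 and HEY2 (median 4.13, camera adjusted p = 0.00814, adjusted p = 0.0538 with an estimated correlation). Genes of other cell types rose with them. Of 10 smooth muscle genes, 7 rose and 3 were not called (median 2.21, camera adjusted p = 5.23e-05, and 0.0378 with an estimated correlation), with ACTA2, an actin of smooth and embryonic heart muscle, 194-fold higher. Of 17 fibroblast and stroma genes, 13 rose, THY1 fell and 3 were not called (median 3.04, camera adjusted p = 5.54e-07, and 0.00723 with an estimated correlation), with POSTN, a matrix protein, at least 239-fold higher. Of 9 epicardial genes, 5 rose and 4 were not called (median 2.90, 2.26 at the floor, camera adjusted p = 0.000695, and 0.0277 with an estimated correlation), among them TBX18, at least 8.39-fold, and WT1, at least 4.78-fold. Of 17 genes of endoderm and liver, SERPINA1, AFP and APOA1 rose, FOXA3 fell and 13 were not called (camera adjusted p = 0.125). Of 14 neural crest genes, 7 rose and 2 fell (camera adjusted p = 0.0832, and 0.0377 with the mean of probe sets, where it was called higher).

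Of 32 cell cycle genes, 30 fell and 2 were not called, MCM5 and TYMS, with a median of -2.04. Their camera adjusted p was 6.69e-14, and 0.00155 with an estimated correlation. CDC20, which starts the exit from mitosis, fell 6.9-fold and MKI67 3.58-fold, to 7.71 ± 0.18. Of 26 pluripotency genes, 23 fell, LEFTY2 rose and 2 were not called (median -3.34, camera adjusted p = 3.51e-10, and 0.00302 with an estimated correlation). LEFTY2, a secreted inhibitor of Nodal signalling, was at 6.57 ± 0.04 in hESC and 11.61 ± 0.06 in CM. Of 16 genes of DNA methylation and Polycomb, 9 fell, TET2 rose and 6 were not called (median -1.39, camera adjusted p = 7.42e-05, and 0.0171 with an estimated correlation), with DNMT3B, a DNA methyltransferase, 45.6-fold lower. Of 20 epithelial genes, 12 fell, 4 rose and 4 were not called (median -1.97, camera adjusted p = 0.0203, adjusted p = 0.0609 with an estimated correlation and 0.0597 with the filter on low values). CDH1 fell 10.8-fold to 8.93 ± 0.01. The 4 that rose were PKP2 and DSP, parts of the desmosomes that also join heart muscle cells, and the keratins KRT8 and KRT18, of which DSP and KRT8 were chosen after their values were seen.

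Among genes of energy metabolism, 9 of 21 genes of fatty acid oxidation rose and 12 were not called (median 0.89, 0.81 at the floor, camera adjusted p = 0.000174, and 0.0274 with an estimated correlation). FABP3, a fatty acid carrier of heart muscle, rose 30.5-fold and PPARGC1A, a regulator of mitochondrial genes, 21.8-fold. Of 35 genes of oxidative phosphorylation, SDHA rose and 34 were not called, yet the list was called higher at a median of 0.45 (camera adjusted p = 3.87e-06, and 0.0175 with an estimated correlation). SDHA rested on a probe set that can hybridize to several transcripts. Without probe sets of its kind (_x_at) its difference was -0.13. All 25 ribosomal protein genes were not called, with a median of -0.33 that became 0.34 under the poly-A spike scaling, which shifted the median of all genes by more (camera adjusted p = 6.81e-05, adjusted p = 0.0609 with an estimated correlation). Cyclic loess also ended this call (median -0.029, adjusted p = 0.383). Of 22 genes of midbrain, hindbrain and spinal cord patterning, 5 rose, among them HOXB2 and HOXB3, and 17 were not called (median 0.25, 0.17 at the floor, camera adjusted p = 0.0343, adjusted p = 0.285 with an estimated correlation).

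The other 11 lists were not called, with camera adjusted p between 0.104 for WNT and BMP feedback genes and 0.847 for primitive streak and mesoderm, but under the poly-A spike scaling WNT and BMP feedback genes were called higher (0.00196), and the neural stem and forebrain lists lower (9.67e-05 and 9.47e-06) while their medians turned from -0.03 to 0.64 and from -0.09 to 0.58, and the forebrain list was also called lower with the filter on low values (0.0144). Calls gained under this scaling or the filter add no support, for the reasons given for NSC versus hESC. The call of oxidative phosphorylation was lost under the poly-A spike scaling (adjusted p = 0.0915), and that of midbrain, hindbrain and spinal cord patterning under quantile normalization, cyclic loess and the beta-actin covariate.

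The comparison of CM with NSC sets the derived populations against each other. Cardiac genes were higher in CM, and neural and cell cycle genes were higher in NSC. Among the largest rises was that of MYL7, an atrial myosin light chain, at 4.60 ± 0.29 in NSC, a mean below the floor, and 15.04 ± 0.03 in CM. RFX4 fell from 11.61 ± 0.12 to 3.55 ± 0.10, at least 115-fold.

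Of 18132 genes, 1963 were called higher in CM and 2146 lower. With the poly-A spike scaling these counts were 2975 and 1286, a share of 69.8% higher in place of 47.8%. Cyclic loess gave 2269 and 1731, a share of 56.7%. The poly-A spikes were lower in CM than in NSC by 0.39, and the beta-actin 3' minus 5' difference was larger by 0.54, each with an exact permutation p of 0.1. Other large rises were those of PLN (at least 655-fold), TNNC1, cardiac troponin C, whose mean in NSC lay below the floor, SMPX (at least 397-fold), MYL2 (738-fold) and MYH6 (704-fold). Other large falls were those of SOX21 (at least 113-fold), SOX2 (225-fold), IL13RA2 (at least 66.0-fold), LIN28A (130-fold) and NEFM, a neurofilament (130-fold).

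Of 27 sarcomere genes, 26 rose and MYOM2 was not called (median 7.05, 6.78 at the floor, camera adjusted p = 1.60e-15, and 0.00156 with an estimated correlation). Of 19 cardiac transcription factors, 14 rose and 5 were not called (median 3.00, camera adjusted p = 4.37e-08, and 0.0054 with an estimated correlation). Of 23 genes of calcium handling and ion channels, 17 rose and 6 were not called (median 2.35, 1.97 at the floor, camera adjusted p = 2.55e-07, and 0.0076 with an estimated correlation), with RYR2, the calcium release channel, at least 31.7-fold higher. Of 9 ventricular markers, 7 rose (median 3.60, camera adjusted p = 1.47e-05, and 0.00936 with an estimated correlation). Of 9 atrial markers, 7 rose and NR2F1, also a neural transcription factor, fell 58.4-fold (median 3.73, 3.56 at the floor, camera adjusted p = 0.0032, adjusted p = 0.0679 with an estimated correlation).

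Of 26 genes of neural stem and progenitor cells, 19 fell, SOX9 rose and 6 were not called (median -3.63, camera adjusted p = 7.71e-08, and 0.0054 with an estimated correlation). PAX6 fell 55.4-fold and SOX3 101-fold, while NES was at 12.67 ± 0.07 in NSC and 12.23 ± 0.06 in CM (log2 difference -0.44, SE 0.05, adjusted p = 3.98e-05) and was not called, though it was with the mean of all its probe sets, at -1.35. Of 27 neuronal genes, 20 fell and 6 were not called (median -2.71, -2.68 at the floor, camera adjusted p = 4.37e-08, and 0.0173 with an estimated correlation). The exception, GAD1, an enzyme that makes the transmitter GABA, rose at least 2.24-fold, from 4.65 ± 0.14 in NSC to 6.08 ± 0.05 in CM. Of 32 cell cycle genes, 28 fell and 4 were not called (median -2.14, camera adjusted p = 7.06e-14, and 0.00156 with an estimated correlation), with MKI67 7.81-fold lower and TOP2A 6.43-fold lower. Of 16 genes of DNA methylation and Polycomb, 8 fell, CBX7 rose and 7 were not called (median -1.05, camera adjusted p = 2.51e-05, and 0.00936 with an estimated correlation), with EZH2, the Polycomb methyltransferase, 8.68-fold lower.

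Epithelial genes were higher in CM than in NSC: 11 of 20 rose and 9 were not called (median 1.95, 1.65 with weak values set to the floor, camera adjusted p = 2.80e-07, and 0.00631 with an estimated correlation), among them KRT19 (57.3-fold) and ESRP1 (at least 12.3-fold). Of the other cell type lists, stroma (12 of 17 rose, median 2.22, camera adjusted p = 1.64e-05, and 0.00936 with an estimated correlation), smooth muscle (7 of 10 rose, median 2.76, camera adjusted p = 1.87e-05, and 0.028 with an estimated correlation) and epicardium (5 of 9 rose, median 2.14, camera adjusted p = 0.000308, and 0.0173 with an estimated correlation) were called higher in CM. Of 21 genes of fatty acid oxidation, 10 rose (median 0.92, camera adjusted p = 2.53e-05, and 0.0141 with an estimated correlation), with FABP3 120-fold higher. Of 35 genes of oxidative phosphorylation, 5 rose and 30 were not called (median 0.58, camera adjusted p = 7.71e-08, and 0.00936 with an estimated correlation). The 25 ribosomal protein genes were not called, with a median of -0.39 (camera adjusted p = 4.90e-05, adjusted p = 0.0595 with an estimated correlation), a call also lost with cyclic loess (median -0.13, adjusted p = 0.127) and under the poly-A spike scaling (adjusted p = 0.197).

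The other 13 lists were not called in this comparison, with camera adjusted p of 0.0778 or more. Alternatives called some of them: glycolysis higher with quantile normalization (0.0243), cyclic loess (0.0118), the mean of probe sets (0.021) and the beta-actin covariate (0.0133), Notch lower with the poly-A spike scaling (2.88e-05), the mean of probe sets (0.0139) and the beta-actin covariate (0.0414), WNT and BMP feedback genes higher with the poly-A spike scaling (0.0114), and endothelium higher with the filter on low values (0.0278). As in the other comparisons, calls gained under the poly-A spike scaling or the filter add no support. In no called list of the 3 comparisons did the median, the mean and the test differ in sign. Among lists that were not called they differed in 6 for NSC versus hESC, 2 for CM versus hESC and 2 for CM versus NSC.

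**Figure D3:**
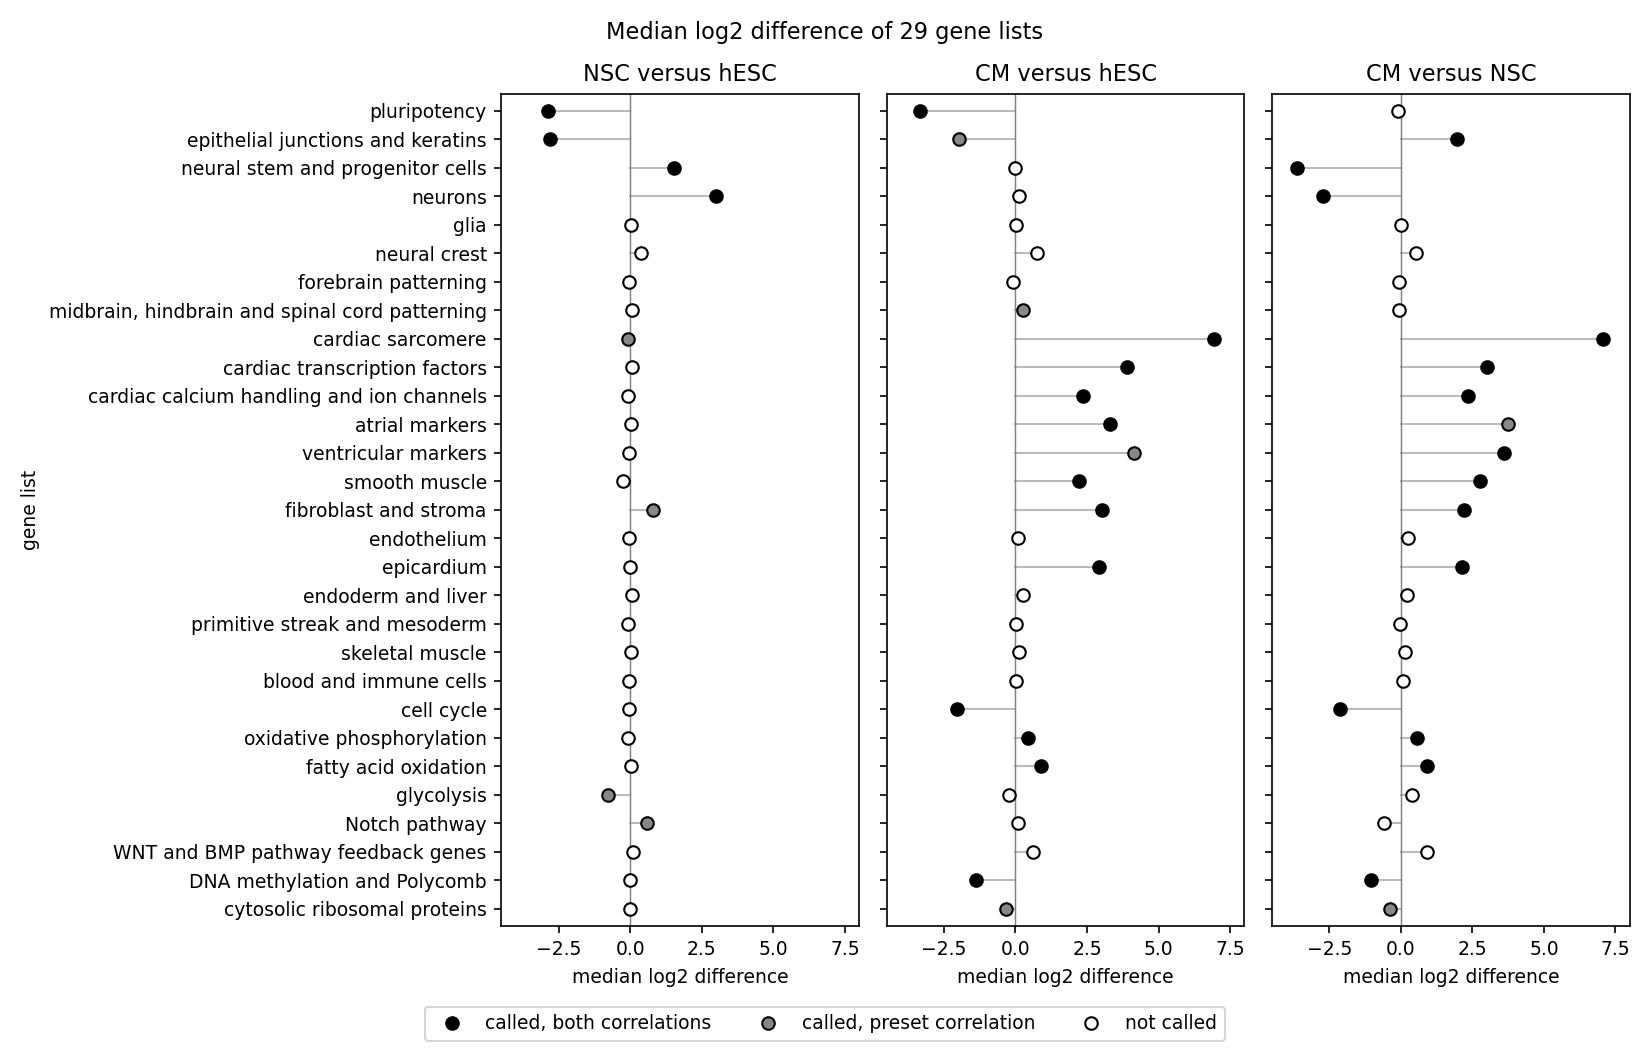
Median log2 difference of each of 29 gene lists in the 3 comparisons, as points with a line from 0, black where called by camera with both correlations, grey with the preset one only and white where not called. The sarcomere list has medians of -0.06, 6.93 and 7.05, the first of which is 0.22 under the poly-A spike scaling.

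Genes that set a group apart from both others were counted for each group. In hESC 793 genes were highest and 691 lowest, in NSC 615 highest and 579 lowest, and in CM 1288 highest and 1232 lowest. Under the poly-A spike scaling 430 were highest and 1330 lowest in hESC, and 2311 highest and 557 lowest in CM. The genes named for hESC were POU5F1P3, POU5F1, APELA, L1TD1 and CNMD, a secreted protein of cartilage. For NSC they were RFX4, IL13RA2, POU3F2, ST18, a zinc finger protein, and HES5, and for CM PLN, SMPX, MYL2, MYOZ2 and MYH6. The smaller of a gene's log2 differences from the other groups was 7.61 for POU5F1, 6.11 for HES5, 9.47 for MYL2 and 9.20 for MYH6, whose signals were above the floor in all groups.

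Genes that changed the same way in NSC and CM were more numerous than independent lists would give. Relative to hESC, 691 genes rose in both, against 166 from independent lists, and 793 fell in both, against 190. Under the poly-A spike scaling these counts were 1330 and 430, and with the mean of probe sets 456 rose in both. In the opposite directions, 96 rose in NSC and fell in CM, against 190, and 158 fell in NSC and rose in CM, against 167. Both comparisons use the same hESC arrays, which by itself makes their differences covary, so unchanged groups were simulated 100 times. The covariance of the differences was 0.565, against a mean of 0.00356 in the simulations, and r across genes, which are not independent replicates, was 0.444 against 0.499. The simulations held array noise only, so they do not cover genes at which hESC themselves stood apart. The excess over independent lists can come from such genes alone. It does not show that NSC and CM changed alike for a common reason.

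**Figure D4:**
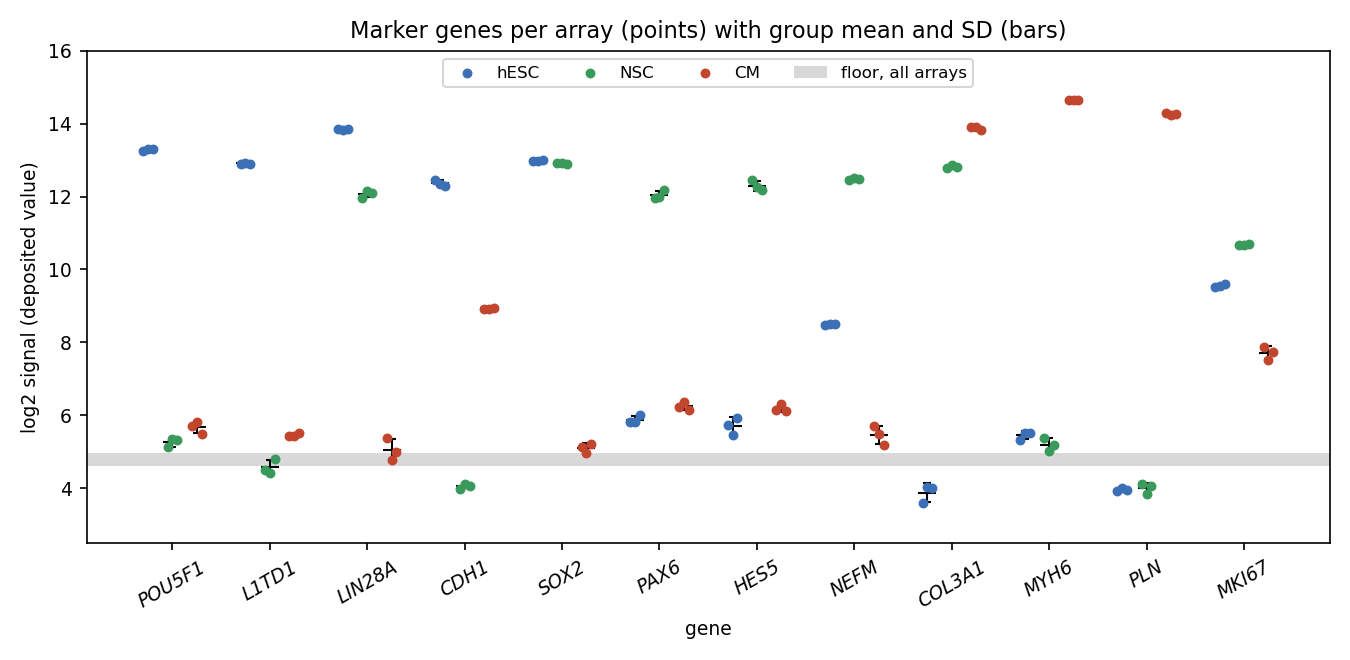
Log2 signal of 12 of the named genes per array (points), with group mean and SD (bars) and the range of the floor over all arrays (grey band). POU5F1 has a mean of 13.29 in hESC against 5.26 in NSC and 5.67 in CM, SOX2 has 12.91 in NSC and 5.10 in CM, and PLN has 3.96, 4.01 and 14.27.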

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

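The tests of the poly-A spikes and of the epithelial genes, and for the stroma genes those of fibroblasts and neural crest, were chosen after the results were seen, while the test of the other probe sets and the splits of the arrays were not.

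The poly-A spikes, control probe sets outside the gene comparisons, were lower in CM than in hESC by a log2 difference of -0.67 (exact two-sided permutation p of 0.1, the smallest possible with 3 arrays against 3). The hybridization controls differed by -0.033, so no fall of that size was seen at their bright signals. This does not decide whether hybridization, washing or scanning was the source. The deposited scale already gave the arrays like medians. These controls also lay at 12.28 in CM, far above the spikes at 7.34. A different amount of spike may have been added to the reactions, since within hESC the spikes already spread over 0.53. A larger share of mRNA in the total RNA of CM is also open, since all 4 spikes were lower, the smallest difference being -0.50, as such a share would give. These cannot be told apart, because no array holds another amount of spike or a measured amount of mRNA.

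The 6 epithelial genes CDH1, EPCAM, CLDN6, ESRP1, ESRP2 and MARVELD2 were higher in CM than in NSC and lower than in hESC, and expression by the cardiomyocytes themselves was not tested. With NSC as the baseline they had 7.22% to 18.9% of their hESC signal in CM, while the upper quartile over 21 pluripotency genes was 0.264%. The 21 were those called lower than hESC in both NSC and CM, which leaves out LEFTY2, so the sets were not chosen alike. Genes still expressed in NSC pull the quartile down, as LIN28A at -41.2%. POU5F1, NANOG, ZFP42 and L1TD1, weak in NSC, had 0.126%, 0.0165%, 0.173% and 0.264%. The shares of these genes argue against undifferentiated cells as the source, although LEFTY1 had 8.88% and GDF3 11.9%. Epicardial or endodermal epithelial cells stay open as a source, since the epicardium list had a median of 2.14 in CM versus NSC, while the endoderm list was not called (adjusted p = 0.106). The highest signals in CM were 8.62 for SEMA3D of the former and 9.70 for APOA1 of the latter, which do not compare as abundance between probe sets.

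Of 17 fibroblast and stroma genes, 8 were higher in NSC than in hESC, with COL3A1 at 12.81 in NSC. COL1A1 and COL1A2, abundant in fibroblasts, differed by -0.55 and 0.24. They were picked from this list after its values were seen, while COL3A1, LUM and DCN of the same list rose. They therefore do not decide whether fibroblasts were mixed into the NSC cultures. Hybridization of the chosen probe sets to other transcripts stays open for the 8 genes as a set, since 62.5% of the other probe sets of these genes (15 of 24, exact 95% binomial interval 40.6% to 81.2%) were called higher and 0 lower, and the interval includes the bound of 50% set for this test. The interval treats probe sets of the same gene as independent, which they are not. All 5 probe sets of COL3A1 and 3 of 4 of DCN were called higher. Neural crest derivatives also stay open. That list had a median of 0.38 and a camera adjusted p of 0.061, and 0.397 with an estimated correlation. Of its 14 genes, 4 rose, 2 fell and 8 were not called. The list was called with the replicate block (0.0353), the mean of probe sets (0.00783) and without hESC replicate 3 (0.0422). Its call under the poly-A spike scaling (0.00853) adds no support, since that scaling shifts all genes of an array alike. Expression by the neural cells themselves was not tested.

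The 10 splits of 6 arrays into groups of 3 are too few for a share under 0.05. Only the real split, 1 of the 10, gave as many called genes in each comparison, with 2897 for NSC versus hESC, 4465 for CM versus hESC and 4109 for CM versus NSC, and the highest of the other splits gave 0. Each other split mixes arrays of groups that stood far apart, which widens the spread it tests against. Its lack of calls follows from that and says nothing on chance.

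The beta-actin 3' minus 5' difference, outside the gene comparisons, was larger in CM than in hESC by 0.63 (exact permutation p of 0.1). Relative to hESC, 96 genes rose in NSC and fell in CM, and 158 fell in NSC and rose in CM. All 254 were called in CM versus NSC, which follows from opposite calls against the same hESC arrays and is no further test. Of the 25 named genes among them, those of muscle were higher in CM than in NSC by 5.78 for TNNI3, 6.55 for ACTC1, 5.33 for TPM1, 6.11 for CNN1, and by 9.80 for TNNC1 and 10.44 for MYL7, whose NSC means lay below the floor, so that these are not measured sizes. Others higher in CM were GJA5 by 2.56 and AFP by 4.45, which were at the floor in NSC and so at least 3.92-fold and 19.4-fold higher, FABP3 by 6.90, PFKP by 3.70, BMP2 by 4.88, PKP2 by 5.14, LEFTY2 by 6.24 and KRT18 by 4.93. AFP was not called in NSC versus hESC without hESC replicate 2 (-0.92), NSC replicate 1 (-0.98) or NSC replicate 3 (-0.99), under the poly-A spike scaling (-0.73) or with the mean of probe sets (-0.75). The mean of probe sets also ended the NSC versus hESC calls of CNN1 (-0.89), GJA5 (-0.70), MKI67 (0.82) and RRM2 (0.67), the poly-A spike scaling that of GJA5 (-0.98), the fit without _x_at probe sets that of RRM2 (0.25), and the test against a log2 difference of 1 those of AFP, MYL7, MKI67 and RRM2 (adjusted p of 1, 0.0761, 0.536 and 0.651). The alternatives covered a gene only in comparisons where the naming rule had picked it. The NSC versus hESC calls of PKP2, NEFM, NHLH2, SP8, LEFTY2, KRT18, SOX3, NRARP, DLL3, UHRF1 and EZH2 were therefore not tested this way. The neural genes NEFM, NHLH2, SP8 and SOX3 had CM minus NSC differences of -7.02, -6.13, -6.98 and -6.66, where NHLH2 and SP8 were at the floor in CM and so at least 53.2-fold and 42.8-fold lower. Those of the Notch genes DLL1, DLL3 and NRARP were -5.84, -3.15 and -3.36, and those of MKI67, RRM2, UHRF1 and EZH2 were -2.96, -2.50, -3.27 and -3.12. The cardiac sarcomere list, called in opposite directions against hESC, had a median of 7.05 in CM versus NSC. Its call as lower in NSC than in hESC was lost with an estimated correlation (adjusted p = 0.119), the filter on low values (0.0569), the mean of probe sets (0.0558), the beta-actin covariate (0.0552) and without NSC replicate 3 and CM replicate 3 (0.0543). Under the poly-A spike scaling, which shifted all genes by 0.28, its median went from -0.06 to 0.22 while its test stayed lower (adjusted p = 0.0214).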

How the results depend on the processing

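Scaling to the poly-A spikes, the beta-actin covariate and the fits without NSC replicate 3 and CM replicate 3 were chosen after the data were seen. Of 307 named gene results 266 kept their direction and their side of the threshold under all alternatives that tested them, and of 87 list results 40 did. Neither kind was tested with probe sets tested singly. Lists were also not tested with the trended robust prior, fits of 2 groups or the 2 other thresholds. The filter on low values dropped some results of both kinds. Counted once per result and alternative, and apart from 2 changes of sign for SDHA and 4 of a median or test for lists, given with their alternatives, named genes lost a call 73 times and gained one 6 times, and lists 22 and 56 times. Of these 56 gains, 34 came with fry, which does not compare a list with other genes. Of called genes with several probe sets, all probe sets were called the same way in 32.9% for NSC versus hESC, 38.6% for CM versus hESC and 39.5% for CM versus NSC. Signals near the floor limit the folds, which are then lower bounds. Except where stated, the cause of a change was not tested.

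Leaving out 1 array at a time gave 1429 to 1447 genes higher and 1448 to 1469 lower in NSC versus hESC, 2066 to 2099 and 2349 to 2398 in CM versus hESC, and 1952 to 1992 and 2122 to 2165 in CM versus NSC. The calls of SDHD in NSC versus hESC (-0.93) and CLDN5 in CM versus NSC (-0.89) were lost without NSC replicate 3, CLDN5 also without CM replicate 3 (-0.99), and EMCN without CM replicate 1, at 0.95 against hESC and 0.79 against NSC. With the replicate block the counts were 1446 and 1451, 2087 and 2378, and 1963 and 2146, the same as without it, and 9, 16 and 16 lists were called. In this balanced layout a block leaves every group difference unchanged. The largest adjusted p of a called gene without it was 0.00691. The gene counts could therefore hardly change and are no check of pairing. By their deviations from the group means, 4 of 9 arrays correlated best with an array of their own number in another group. With the beta-actin covariate 1439 and 1457, 2057 and 2480, and 1954 and 2220 genes were called higher and lower. Without NSC replicate 3 and CM replicate 3 these were 1430 and 1469, 2079 and 2398, and 1999 and 2156.

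With the mean of probe sets per gene, 456 genes were higher in both NSC and CM, and 101 were lower in NSC and higher in CM. With probe sets tested singly, which counts a gene several times, 3368 were higher and 3208 lower in NSC versus hESC, 4999 and 5823 in CM versus hESC, and 4551 and 5351 in CM versus NSC. Without _x_at probe sets SDHA turned to -0.13 against hESC and -0.12 against NSC. With the adjusted p alone, which drops the fold threshold, these counts were 5210 and 5059, 5870 and 6191, and 5650 and 6069. Of group-specific genes it gave 3280 highest in hESC, 3074 in NSC and 3983 in CM, and 2424 lowest in NSC and 4326 in CM. It gave 2894 higher in both NSC and CM, 1467 higher in NSC and lower in CM, and 1096 the other way. A test against a log2 difference of 1 (treat), stricter by construction, gave 59 and 103 for these opposite changes.

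Under the poly-A spike scaling, which shifts whole arrays, 4639 genes were higher and 1091 lower in CM versus hESC, and 2975 and 1286 in CM versus NSC. It gave 430 genes highest in hESC, 2311 highest and 557 lowest in CM, and 1330 higher in both NSC and CM. By this shift alone, of 0.28 and 0.67, the median of the sarcomere list became 0.22 in NSC versus hESC, where its test stayed lower, and that of the ribosomal list 0.34 in CM versus hESC. With an estimated correlation 4 lists were called in NSC versus hESC. With fry, which does not compare a list with other genes, 23, 27 and 26 lists were called. Among the lists that it called, the direction of its test was opposite to camera's for primitive streak and mesoderm in NSC versus hESC (median -0.081) and for glia in CM versus hESC (median 0.0085).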

Other observations

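All tests in this part were chosen after the results were seen, and of the 12 gene families tried none was called with an estimated correlation.

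Of 10 metallothioneins, which bind zinc and copper, some were lower in each derived population. In NSC 6 of 10 fell and 0 rose, with a median of -1.57 (camera adjusted p = 0.00152, adjusted p = 0.23 with an estimated correlation), and in CM 5 fell and MT3 rose, with a median of -0.98 (camera adjusted p = 0.0174, adjusted p = 0.283 with an estimated correlation). The medians kept their sign under all 4 scalings, though that in CM was -0.30 under the poly-A spike scaling. MT1G, at 12.19 ± 0.04 in hESC, fell by 4.91 on the log2 scale in NSC and by 5.19 in CM. In NSC, 6 of 14 imprinted genes rose and 1 fell (camera adjusted p = 0.0182, adjusted p = 0.23 with an estimated correlation), with PLAGL1, a zinc finger protein, rising from 6.23 ± 0.15 to 12.03 ± 0.06.

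In CM versus hESC, 22 of 43 collagen chains rose and 3 fell, with a median of 1.21 (camera adjusted p = 0.000417, adjusted p = 0.192 with an estimated correlation). Of 10 laminin chains, 5 rose and 1 fell (camera adjusted p = 0.0293, adjusted p = 0.192 with an estimated correlation), and of 20 integrin chains 10 rose and 2 fell (camera adjusted p = 0.0159, adjusted p = 0.238 with an estimated correlation). ITGAV, an integrin chain that binds fibronectin and vitronectin, rose from 10.13 ± 0.06 to 13.17 ± 0.07.

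A candidate explanation for the HOX genes called in NSC is a hindbrain-like position along the neural axis, which paralogous groups 1 to 4 mark. Of 8 measured genes of these groups, 3 were called higher in NSC than in hESC, against 0 of 19 of the other groups (Fisher's exact test, two-sided, p = 0.0191). The test decides nothing on this, because the same genes prompted it and HOX genes lie in clusters. HOXB2 and HOXB3 were also higher in CM than in hESC, so that these genes alone do not mark a neural position.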
